A study of Mus musculus with 2 samples.

How the data were processed

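Total RNA of hippocampus tissue was sequenced as microRNA libraries, with a fragment size below 30 nt per the labels. The samples were 2 biological replicates of male B6CASTF1/J mice at 10 days, each labelled with 3 males. The labels give 1 group, and the replicate numbers were taken from them.

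The deposited files hold raw read counts per microRNA gene and library, 1 file per library. Per the submitters' notes deposited with the counts, the genome was mm10 and the annotation was GENCODE M21, and each count file was derived from the reads of its own library, so replicates were not pooled. The aligner, the counter, their versions and any adapter trimming are not given in the sources used here. Each file has 3 columns of counts, unstranded and for each strand, and 4 lines of totals for reads that were unmapped, fitted several places, fell outside genes or were ambiguous. This is the layout of STAR's gene counts, but no source names the tool. The sense column was not named in the sources used. By a rule fixed before the data were examined, it was the stranded column with the larger total over genes. The gene counts leave out reads that align to several places, which form a total of their own.

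All 2202 gene identifiers matched GENCODE M21 (GRCm38), which gave symbols, positions, host genes and hairpin sequences. A host gene was an annotated gene that contained the whole hairpin on the same strand, with small RNA genes and pseudogenes, among others, left out. Genes called intergenic had no such host, whatever lay on the other strand. Genes sharing at least 20 consecutive bases with another microRNA gene, both read in their own sense orientation, were marked as near-identical copies, and 1084 genes were so marked. Of the 1405 genes with 0 counts in both libraries, 940 were among them. Shares of lists whose members have copies are shares of uniquely assigned reads and can lie below the true level. Whether reads from CAST/EiJ alleles that differ from the reference were counted less often was not analysed here.

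Of all 12369585 reads in replicate 1, 38.9% were counted on genes, 37.7% fitted several places, 5.74% fell outside genes and 17.7% were unmapped. Of the 10106239 reads in replicate 2, these shares were 34.6%, 39.8%, 6.09% and 19.5%. The lines of totals were left out of library sizes and tests. CPM was computed from the deposited counts as counts per 1000000 counts on genes. A limit for a count of 0 was set at 3 counts. Shares of counts per library had exact Clopper-Pearson intervals at the 95% level.

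Genes with at least 10 counts over both libraries were compared by an exact two-sided binomial test given the library totals. P-values were adjusted by Benjamini-Hochberg, and a gene was said to differ at an adjusted p below 0.05 with an absolute log2 ratio of at least 1. Log2 ratios are replicate 2 over replicate 1 with 0.5 counts added. The common biological coefficient of variation was estimated in edgeR with an intercept-only design and TMM factors over genes with at least 10 counts in both libraries. Correlations used log2 of CPM with a pseudocount of 1. The median log2 ratio of each of 24 lists was placed among 10000 random lists of the same size, drawn within 10 groups of mean expression. This describes these libraries and is not a test of conditions. Random lists draw genes singly, so a list of neighbours that vary together can be placed too far out.

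The lists and the rule for named genes were fixed before the data were examined. Named genes were the 15 with the highest mean CPM, the 3 most abundant members of each list, the 5 with the highest and the 5 with the lowest log2 ratio among differing genes with a mean of at least 100 counts, and the highest and lowest tested member of each of the 8 most abundant clusters. A cluster was a run of at least 3 genes on a strand with at most 10000 bases between neighbours. Genes outside this rule were named after their values were seen.

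The steps were tested on simulated data with the real means and library sizes, except that list ratios were drawn independently for each gene. In the comparison of libraries, 91 of 100 genes changed 4-fold and 8 of 100 changed 1.5-fold were called, with the ratio minimum in force. Of 354 unchanged genes, 0 were called, and 27 passed the adjusted p alone. These counts held counting error only, so the 0 does not give the rate of false calls at the spread of the real libraries. Of 100 unchanged lists of 6 genes, 4 fell outside the 2.5 to 97.5 percentiles, and 99 of 100 lists raised by 1.5 on the log2 scale lay above them. A simulated coefficient of variation of 0.5 was recovered as 0.484 over 414 genes.

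Alternatives covered the scaling (library totals, TMM, DESeq2 size factors), filters on low counts, the ratio minimum, detection thresholds, the denominator, unstranded counts, pseudocounts, genes with copies and each replicate left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used. Signal tracks named in the submitters' notes were not used here.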

Results

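MicroRNA sequencing was used to profile the hippocampus of male B6CASTF1/J mice at 10 days of age. This strain name denotes the first-generation hybrid of C57BL/6J and CAST/EiJ mice. The labels describe 1 group of 2 biological replicates. Each replicate is labelled with 3 males. The labels list different animal numbers for the 2 replicates but give both the same donor identifier, so SD and coefficients of variation describe the spread between these samples, which may in part be technical. MicroRNAs are small RNAs that are cut from hairpin precursors and repress target transcripts. The deposited values were read counts for 2202 hairpin genes, so the mature products of the 5' and 3' arms of a hairpin were not separated. Replicate 1 had 4815761 counts on microRNA genes and replicate 2 had 3495401. At this depth a count of 0 allowed a level of up to 0.623 CPM (counts per 1000000 counts on genes) in replicate 1 and up to 0.858 CPM in replicate 2, where intervals and limits of this kind cover counting error only. With 1 group, the data address which microRNAs the tissue contained and how far the 2 libraries differed, and they hold no contrast between conditions. A sign-flip test over 2 libraries cannot give a p below 0.5.

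Among reads assigned to a single gene, let-7 microRNAs, the microRNAs of the imprinted Dlk1-Dio3 region and the miR-99, miR-100 and miR-125 families took large shares. Reads that fit several places, 0.968 per counted read in replicate 1 and 1.15 in replicate 2, are outside these shares, so microRNAs with several copies can rank too low. Levels here and below are read counts, and whether different microRNAs were captured equally well was not analysed. The let-7 family, whose members accumulate as cells leave proliferation, took 25.4% ± 2.03 of counts (SD, n = 2). The Dlk1-Dio3 microRNAs, expressed from the maternally inherited chromosome, took 22.6% ± 2.15 (SD, n = 2). The miR-99, miR-100 and miR-125 families took 11.3% ± 3.10 (SD, n = 2). The microRNAs described as enriched in neurons or brain, called the neuronal list here, took 9.46% ± 1.73 (SD, n = 2). In total 442 genes reached 2 CPM in both libraries, and the 110 genes with a mean of 1000 CPM or more held 95.3% of counts. Of the detected genes, 220 lay in an intron of a host gene on the same strand, 102 in an exon, and 120 had no host gene on that strand.

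Mirlet7b had the highest mean level, at 86792 ± 18311 CPM (SD, n = 2), although in replicate 1 Mir99a (91288 CPM) and Mir127 (84779 CPM) lay above it (73844 CPM). It lies on chromosome 15 at 85707319-85707403 (mm10, as for all positions), in an exon of the noncoding transcript Lncppara. Mirlet7i, an intergenic gene on chromosome 10 at 122985640-122985724, reached 70380 ± 2682 CPM, and Mirlet7g, in an intron of Wdr82, reached 51571 ± 1830 CPM (SD, n = 2 for both). Mirlet7d and Mirlet7e followed at 20288 ± 948 and 16110 ± 4270 CPM (SD, n = 2 for both). Mir99a, in an intron of its host transcript on chromosome 16 at 77598936-77599000, reached 75518 ± 22303 CPM (SD, n = 2). Of the same families, Mir99b reached 14805 ± 10362 CPM and Mir100 reached 12045 ± 3033 CPM (SD, n = 2 for both). Of the 12 let-7 genes, 6 share at least 20 consecutive bases with another microRNA gene. Reads that fit several genes were not in the gene counts, so those 6 levels are uncertain and can lie below the true level.

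Among the microRNAs of the neuronal list, Mir139 and Mir149 were the most abundant. Mir139, in an intron of the phosphodiesterase gene Pde2a on chromosome 7 at 101475376-101475443, reached 44583 ± 18050 CPM (SD, n = 2). Mir149, in an intron of the proteoglycan gene Gpc1 on chromosome 1 at 92850378-92850443, reached 22382 ± 4421 CPM (SD, n = 2). Mir132, a microRNA induced by neuronal activity, reached 7062 ± 4065 CPM, and Mir138-1, which shares bases with a second copy, reached 5734 ± 1892 CPM (SD, n = 2 for both). The activity-regulated list, which shares Mir132 and Mir138-1 with the neuronal list, took 2.38% ± 0.194 of counts (SD, n = 2). Of the 20 neuronal genes, 14 share bases with another gene, among them the 3 Mir124a genes, which are well known as neuronal and were named after their values were seen. These 3 held 17 counts in replicate 1 and 17 in replicate 2. The neuronal share is therefore a share of uniquely assigned reads.

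**Figure D1:**
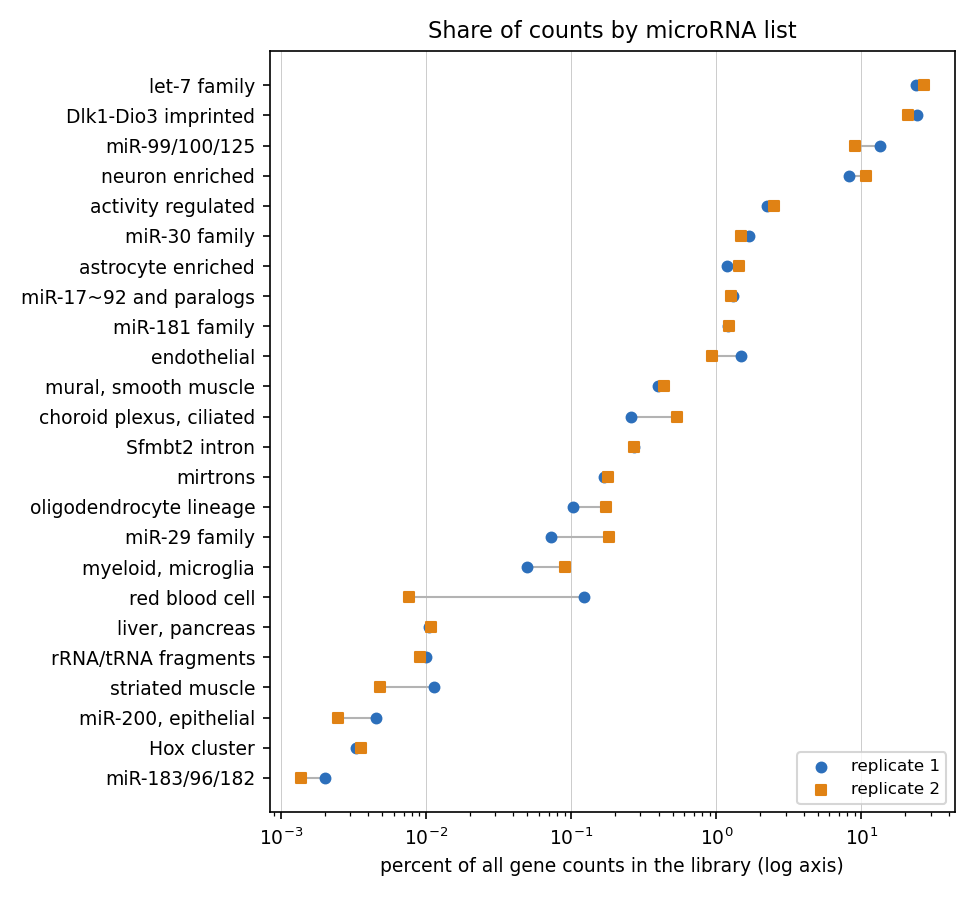
Percent of microRNA gene counts taken by each list fixed before the data were examined, for the 2 hippocampus libraries, on a log axis. The let-7 family (mean 25.4%) and the Dlk1-Dio3 microRNAs (22.6%) lie highest, and the miR-183 cluster lies lowest (0.00169%).

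MicroRNAs of glia, blood vessels and proliferating progenitors were present at lower shares. Mir126a, the endothelial microRNA encoded within Egfl7, took 1.21% ± 0.395 of counts (SD, n = 2), and its opposite-strand partner Mir126b had 0 counts in both libraries. The mural and smooth muscle list, led by Mir143 at 3946 ± 176 CPM, took 0.418% ± 0.0303 (SD, n = 2). The astrocyte list took 1.31% ± 0.172 and was led by Mir23a, whose bases are shared with a copy, and by Mir143 (SD, n = 2). That list has members in common with the mural, miR-29 and choroid plexus lists. The oligodendrocyte list took 0.139% ± 0.0497, led by Mir219a-2, which shares bases with a copy, at 779.8 ± 298.7 CPM and by Mir338 at 579.8 ± 212.1 CPM (SD, n = 2). The myeloid list took 0.0701% ± 0.0291 and was led by Mir150 at 574 ± 285 CPM, followed by Mir155 at 81.2 ± 4.12 and Mir142 at 37.1 ± 5.96 CPM (SD, n = 2). The miR-17~92 cluster and its paralogs, associated with proliferating progenitors, took 1.29% ± 0.0357, with Mir93 at 4823 ± 69.2 and Mir17 at 3891 ± 564 CPM (SD, n = 2).

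Other families were measured at levels from about a percent downwards. The miR-30 family took 1.58% ± 0.128, led by Mir30d, and the miR-181 family took 1.21% ± 0.0194 (SD, n = 2). Mir181d was the highest miR-181 gene in replicate 1, and Mir181b-2, which shares bases with a copy, was the highest in replicate 2. The microRNAs of the Sfmbt2 intron took 0.271% ± 0.00147, with Mir467d the highest, but 79 of those 81 genes share bases with another gene (SD, n = 2). Mirtrons, which are cut from short introns by splicing, took 0.174% ± 0.00832 (SD, n = 2), with Mir1981 the highest in replicate 1 and Mir877, in Abcf1, the highest in replicate 2. The miR-29 family took 0.127% ± 0.0770, and Mir29a made up most of it (SD, n = 2).

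MicroRNAs of liver, pancreas and striated muscle, not expected in brain, and those of some further lists took small shares of the uniquely assigned reads. The list of liver and exocrine pancreas microRNAs took 0.0106% ± 0.000276, and Mir122, the main liver microRNA, reached 35.5 ± 5.65 CPM (SD, n = 2). The striated muscle list took 0.00809% ± 0.00460, most of it from Mir206 at 67.5 ± 49.3 CPM (SD, n = 2). Of its 10 genes, 5 share bases with another gene, among them the Mir1a and Mir133a genes, which had 0 counts and were named after their values were seen, so this share can lie below the true level. The same limit holds for 2 of the 8 liver and pancreas genes and 2 of the 5 Hox genes. The miR-200 list of epithelia took 0.00347% ± 0.00143, led by Mir200c, and the microRNAs of the Hox clusters took 0.00341% ± 0.000189, led by Mir10b (SD, n = 2). The miR-183 cluster of sensory organs took 0.00169% ± 0.000453, and Mir96 had 0 counts in both libraries (SD, n = 2). Loci whose reads are known to come from ribosomal or transfer RNA took 0.00956% ± 0.000609, led by Mir6236, while Mir690 had 0 counts in both libraries (SD, n = 2).

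Within the Dlk1-Dio3 region of chromosome 12, microRNA genes of a single strand differed widely in level. The proximal cluster at 109563692-109595388 holds 14 genes and took 12.4% ± 3.78 of counts (SD, n = 2). Its highest gene was Mir127, at 60925 ± 33735 CPM, and its lowest tested gene was Mir3070a, which shares bases with a copy, at 14.6 ± 7.20 CPM (SD, n = 2 for both). Mir770, in an exon of the noncoding gene Meg3, reached 35984 ± 8807 CPM and Mir433 reached 15919 ± 2584 CPM (SD, n = 2 for both). The distal cluster at 109709060-109747960 holds 39 genes and took 9.73% ± 1.66 (SD, n = 2). Its highest gene on average was Mir487b, at 24929 ± 21196 CPM (SD, n = 2), which shares bases with 1 other gene. Mir382, in an exon of the noncoding gene Mirg, had 17017 ± 140 CPM (SD, n = 2). In replicate 1 Mir382 lay above Mir487b (17117 against 9941 CPM), so the rank of Mir487b rests on replicate 2.

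**Figure D2:**
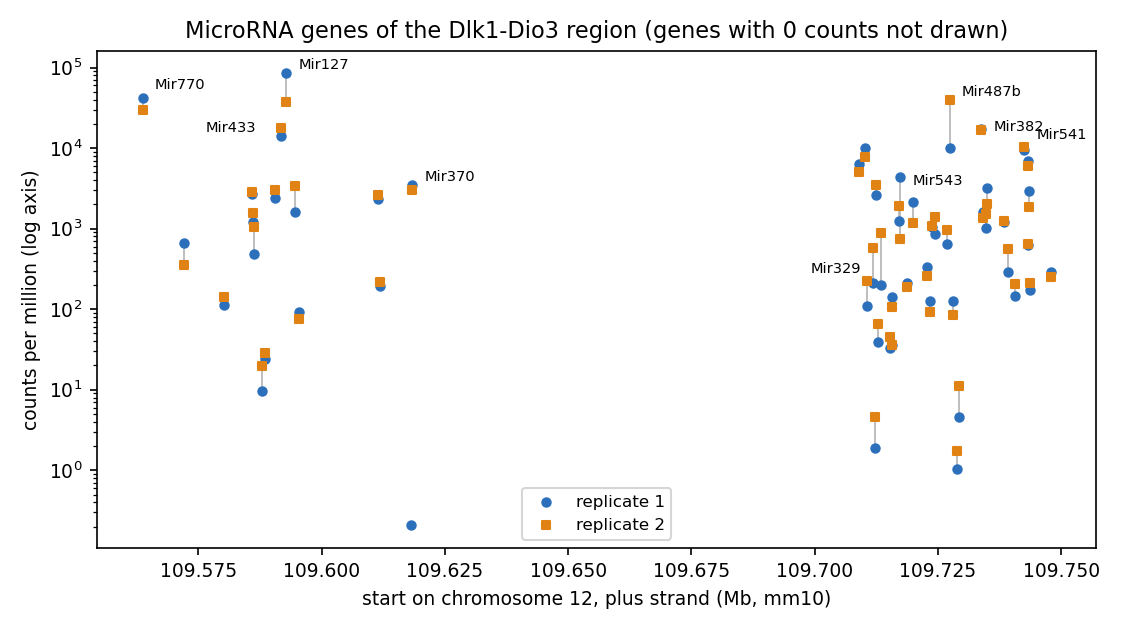
CPM (log axis) of the Dlk1-Dio3 microRNA genes against their start on chromosome 12 (Mb, mm10), with circles for replicate 1, squares for replicate 2 and a line joining both values of a gene; values of 0 are not drawn. Mir127 lies highest in replicate 1 and Mir487b in replicate 2, and Mir543 is separated by -2.56 on the log2 scale.

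Of 6 smaller clusters outside that region, 5 held genes that differed more than 10-fold in mean level of uniquely assigned reads. All these ratios compare read counts of different microRNAs, and equal capture of these was not analysed. On chromosome 17 at 17830188-17830879, Mirlet7e, Mir99b and Mir125a lie within Spaca6 and together took 3.86% ± 0.194 (SD, n = 2), and their mean levels differed by up to 2.09 times. Within single libraries they differed more, with Mir99b at 4.64 times Mir125a in replicate 1 and Mirlet7e at 2.56 times Mir99b in replicate 2. On chromosome 13 at 48536012-48538272, Mirlet7d was 298 times as abundant as Mirlet7f-1, which shares bases with 2 other genes. On the same chromosome at 63300484-63301275, Mir23b was 219.4 times as abundant as Mir24-1, and each of these shares bases with 1 copy. In both chromosome 13 clusters, reads that fit several genes were left out, so these ratios are uncertain and may reflect that loss. On chromosome 14 at 115043671-115044506, Mir17 was 16.9 times as abundant as Mir18. On the X chromosome at 7237683-7248497, within Clcn5, Mir532 was 38.9 times as abundant as Mir362 on average, 61.6 times in replicate 1 and 26.8 times in replicate 2. On chromosome 5 at 138165321-138165818, within Mcm7, Mir93 was 35.8 times as abundant as Mir25 on average, 53.1 times in replicate 1 and 27.2 times in replicate 2.

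The second question was how far the 2 libraries differed beyond counting error. By its median, the red blood cell list was lower in replicate 2, and the lists of choroid plexus and ciliated cells, of the miR-29 family and of astrocytes were higher there. The members that passed the test numbered 2 of 3, 3 of 6, 3 of 4 and 3 of 8. Mir449a, the most abundant member of the choroid plexus and ciliated cell list, and Mir23a and Mir143, the most abundant of the astrocyte list, did not pass. Of 540 genes with at least 10 counts in total, 101 differed by an exact two-sided binomial test with Benjamini-Hochberg adjustment and an absolute log2 ratio of at least 1. Of these, 62 were higher in replicate 2 and 39 in replicate 1, a share of 61.4% higher in replicate 2. That share was 53.1% with TMM sizes and 44.4% with DESeq2 size factors, so the split between directions depended on the scaling. The median log2 ratio over tested genes was 0.17 with library totals, 0.10 with TMM sizes and 0.00095 with DESeq2 factors. The test compares these libraries, not conditions.

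Across the 540 genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.976 and Spearman's rho was 0.954. The log2 ratio had a median absolute value of 0.54, and 75.9% of genes lay within 2-fold. The common biological coefficient of variation from edgeR was 38.6% over 427 genes. A chi-square of 459040 over these genes showed that the libraries differed by more than sampling noise, so they were not 1 library deposited under 2 labels.

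**Figure D3:**
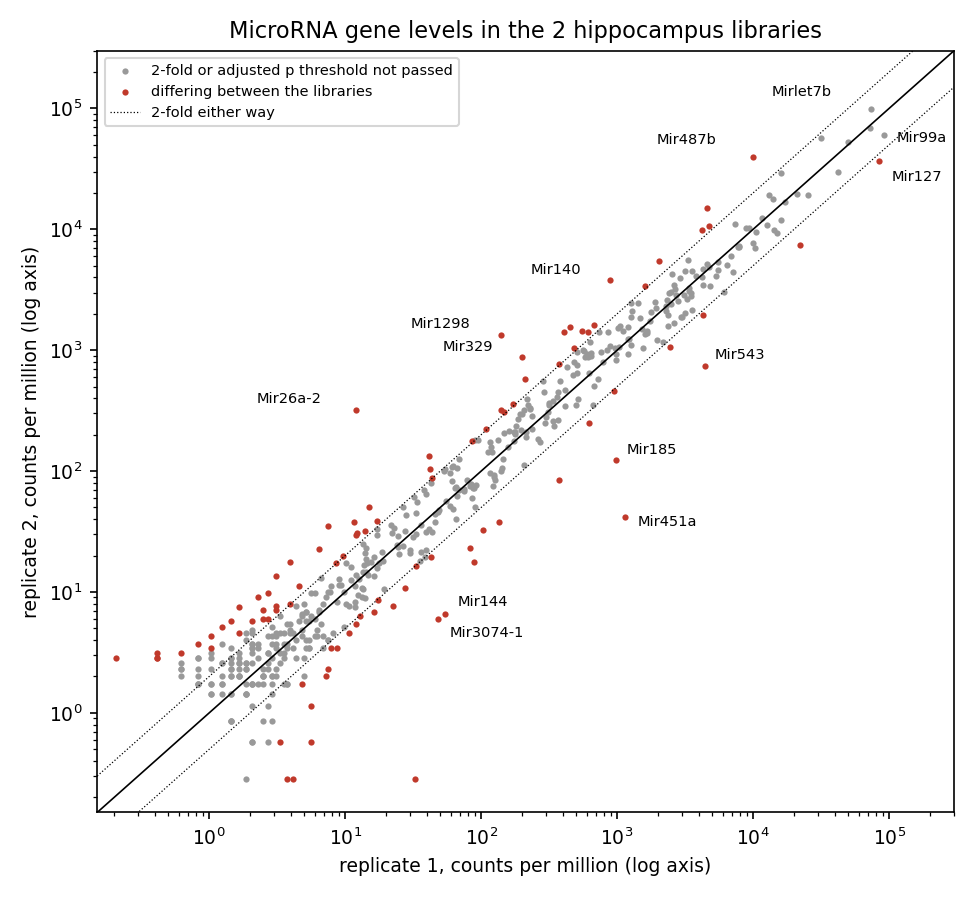
CPM of each tested microRNA gene in replicate 1 (x) and replicate 2 (y), both on log axes, with differing genes in red, the line of equality and dotted lines at 2-fold; genes with a count of 0 in either library are not drawn. Mir451a, Mir185 and Mir543 lie below the lines, and Mir26a-2, Mir1298 and Mir329 lie above them.

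Among differing genes with a mean of at least 100 counts, Mir451a lay lowest in replicate 2. This red blood cell microRNA, an intergenic gene on chromosome 11 at 78073170-78073241, had 1143 CPM in replicate 1 and 41.5 CPM in replicate 2, a log2 ratio of -4.78. Mir144, its neighbour at 78073005-78073070, had a log2 ratio of -3.02. Both passed the test, and the median log2 ratio of the 3 red blood cell genes lay at the 0.02 percentile of 10000 random lists matched on expression. Those random lists do not allow for neighbours such as these. The number differing was 2, and it was 2 when adjusted over the list alone. The list took 0.123% of counts in replicate 1 and 0.00764% in replicate 2. Mir486, the remaining member, had a log2 ratio of -0.15 and did not pass, and its bases are shared with a copy on the opposite strand. Under the same minimum of counts, the next lowest ratios among differing genes were those of Mir185 in an intron of Tango2 (-2.99), Mir3074-1 (-2.96) and Mir543 (-2.56), where Mir3074-1 shares bases with a copy.

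In the other direction, Mir26a-2 had the highest ratio among differing genes with a mean of at least 100 counts, with 58 counts in replicate 1 and 1126 in replicate 2, a log2 ratio of 4.73. It shares bases with 1 other gene, so this value is uncertain. Mir1298, in an intron of the serotonin receptor gene Htr2c on the X chromosome at 147064905-147065002, had a log2 ratio of 3.27. Under that minimum of counts, Mir329, Mir140 and Mir487b followed at 2.14, 2.11 and 2.01. Choroid plexus and ciliated cell microRNAs took 0.258% of counts in replicate 1 and 0.533% in replicate 2. The median log2 ratio of the 6 tested members was 1.44, at the 99.9 percentile of random lists, and all 6 lay above 0. Mir449a lies in a run of 3 neighbouring microRNA genes and Mir34c in a run of 2. The random lists do not allow for neighbours, so this percentile can lie too far out. Without Mir34b, Mir34c and the Mir449 genes, an alternative chosen after seeing the data, the median of the 2 members left was 2.16 at the 97.1 percentile, inside the range of 2.5 to 97.5. Mir204, in an intron of Trpm3, had a log2 ratio of 1.79, while Mir449a and Mir34c, at 0.80 and 0.92, did not pass. Members differing numbered 3, and 4 when adjusted over the list alone. Mir34b and Mir211 passed beside Mir204, and Mir449c passed over the list alone. These 3 were named after their values were seen, and Mir211 rests on 2 and 10 counts.

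The miR-29 family had a median log2 ratio of 1.23, at the 99.2 percentile of random lists. Mir29a and Mir29b-1 are neighbours, as are Mir29c and Mir29b-2, and the random lists do not allow for this. Mir29a (1.40), Mir29c (1.06) and Mir29b-1 (1.69) differed, 3 of 4 genes and also 3 when adjusted over the list alone. Mir29c and Mir29b-1 share bases with other genes, so their values are uncertain. Mir29b-1 was named after its value was seen, and Mir29c did not pass with TMM sizes (0.99) or DESeq2 factors (0.89). The astrocyte list had a median of 0.87, at the 99.3 percentile, but its summed counts took 1.18% in replicate 1 and 1.43% in replicate 2, a log2 ratio of 0.27. Its most abundant member, Mir23a, had a log2 ratio of -0.27, and Mir143 had 0.09. Of its 8 genes Mir21a, Mir29a and Mir29b-1 differed, also 3 when adjusted over the list alone. Mir29a and Mir29b-1 are miR-29 genes, and Mir21a was named after its value was seen. Without the members shared with other lists, an alternative chosen after seeing the data, its median was 0.95 at the 96.5 percentile, inside the range of 2.5 to 97.5. With 24 lists, some are placed outside that range by chance.

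**Figure D4:**
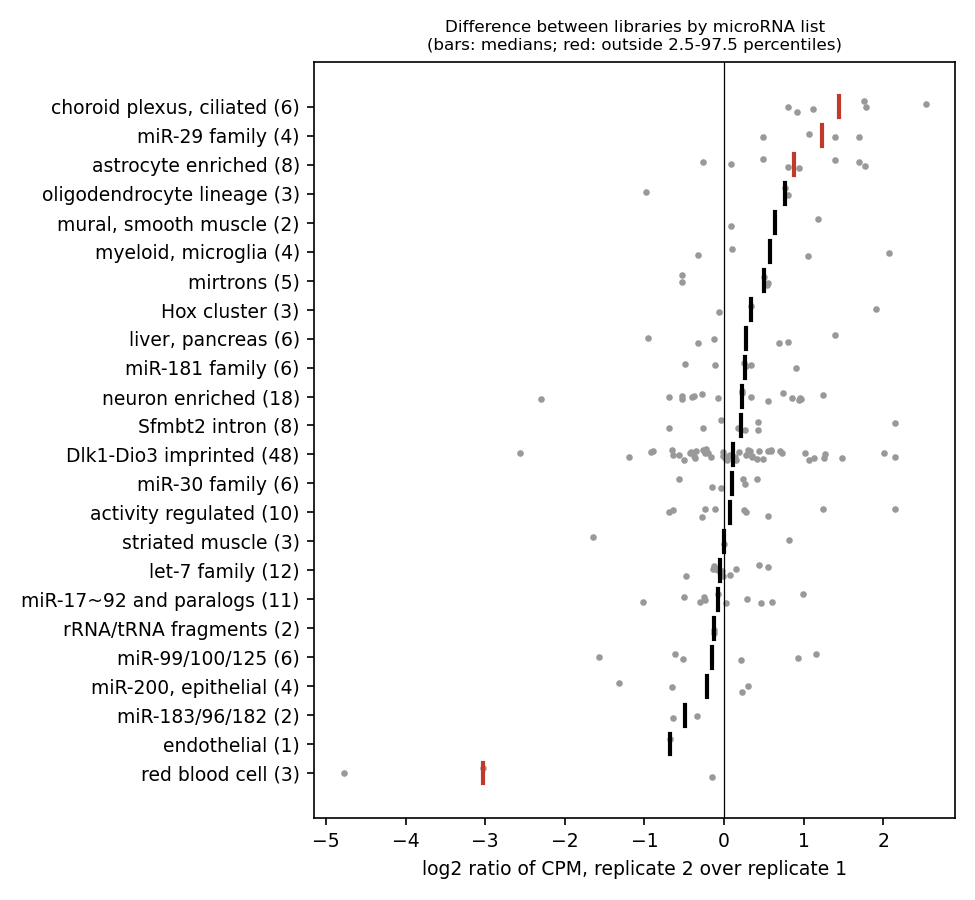
Log2 ratio of CPM, replicate 2 over replicate 1, for each tested member (points) and the median (bar) of each list, with the number of members in brackets and red bars for medians outside the 2.5 to 97.5 percentiles of random lists. The red blood cell list lies lowest (median -3.02) and the choroid plexus and ciliated cell list highest (1.44).

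The Dlk1-Dio3 list as a whole had a median log2 ratio of 0.11, at the 60.8 percentile, with members on both sides. Of 48 tested genes 9 differed, and 10 did when adjusted over the list alone. Mir127 (-1.19) and Mir543 (-2.56) were lower in replicate 2, and 7 genes, among them Mir487b and Mir329, were higher. With TMM sizes 5 were higher and 2 lower, and with DESeq2 factors 4 were higher and 4 lower. In the miR-99, miR-100 and miR-125 families, Mir99b (-1.57) and Mir125a (1.16) differed in opposite directions although they lie in the same cluster, but Mir125a did not pass with DESeq2 factors (0.99). Of the neuronal list Mir132 (1.25) was higher in replicate 2, and Mir153 (-2.30), named after its value was seen, was lower. The activity-regulated list had 2 differing genes, Mir132 and Mir329. The numbers for the neuronal, activity-regulated and miR-99, miR-100 and miR-125 lists were the same, 2 each, when adjusted over the list alone.

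None of the 12 let-7 genes differed with library totals, TMM sizes or DESeq2 factors, and their log2 ratios had a median of -0.05. In the myeloid list, Mir150 (1.06) and Mir223 (2.08) were higher in replicate 2, although Mir150 did not pass with TMM sizes (0.99) or DESeq2 factors (0.89). Mir223 was named after its value was seen. Mir145a (1.18) of the mural list was higher in replicate 2, whereas Mir206 (-1.65) of the striated muscle list and Mir200c (-1.32) of the miR-200 list were lower. Mir106a (-1.01) of the miR-17~92 list and Mir669e (2.14) of the Sfmbt2 list, which shares bases with a copy, also differed, and both were named after their values were seen. Each of these last 5 lists had 1 differing gene, also when adjusted over the list alone, and the myeloid list had 2. No gene of the miR-30, miR-181, mirtron, endothelial, Hox, miR-183 or ribosomal and transfer RNA lists differed under any of the 3 scalings. In the oligodendrocyte and liver and pancreas lists none differed with library totals, but Mir219a-1 (-1.05 with TMM sizes), which shares bases with a copy, and Mir216a, named after its value was seen, did with the other scalings.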

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

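Several tests were chosen after the results were seen. These were the tests of Mir144, of counting error in Mir451a and Mir204, of genes matched on hairpin GC content and length and of multi-copy genes. So were the tests of the Htr2c microRNAs under other scalings and against random lists, and the list without Mir34b, Mir34c and the Mir449 genes. The Mir124a, Mir9, Mir34b, Mir211, Mir448 and Mir1912 genes were named then. The linear trend on GC content and length and the Htr2c microRNAs with library totals were set out before their results were seen. Mir1298, in an intron of Htr2c, had already been seen by then.

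Reads that the gene counts leave out, and counts in the antisense column, were far above the limit of 3 counts. Reads that fit several places numbered 4660508 in replicate 1 and 4020799 in replicate 2. Uniquely aligned reads outside the microRNA genes numbered 709413 and 615581. The antisense column held 281272 and 212165 counts, of which 281108 and 212068 lay at the 64 genes with a microRNA gene on the opposite strand. These equal the numbers of reads that were ambiguous without strand, so they were already counted in sense at the partner gene. In replicate 1 Mir126b had 71687 antisense counts, against 71696 sense counts of Mir126a. At genes with no such partner the antisense column held 164 and 97 counts. There were no control samples among those used here to set these values against.

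MicroRNA genes with near-identical copies had low counts by their median, though not each of them, since Mir138-1, which has a copy, reached 5734 CPM on average. In the fixed lists of conserved families and neuronal microRNAs, the median level of 35 single-copy genes was 23.8 times that of 35 genes sharing bases with another, and the Mir124a and Mir9 genes held 4.197 ± 0.943 and 101 ± 6.91 CPM in sum (SD, n = 2 for both). This ratio is the pattern itself, so it decides between no explanations. Reads that fit several copies are left out at any level of expression, so these low counts do not show that such microRNAs are little expressed at this age. How far the loss of reads and low expression each contribute stays open, because the reads left out, 105.9% of those counted on genes, carry no gene name. No biological explanation was tested, since the design has 1 group.

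Of the 3 red blood cell microRNAs, Mir451a and Mir144 were lower in replicate 2. Counting error was excluded for Mir451a, whose log2 ratio had an upper 95% bound of -4.55. Mir451a had already passed the exact test on the same counts, so this bound is no second test. For hairpin GC content or length, the 50 genes nearest to each member in both were pooled. Their median log2 ratio was 0.10 (95% bootstrap interval -0.04 to 0.28), against -3.02 for the list, so as a set they did not share the shift. A median over so broad a set could hardly reach that of the list, so GC content or length was not excluded. A linear trend on GC content and length decided nothing, since it explained 0.857% of the variance, and the list median was -3.18 with it removed. More red blood cells in the tissue of replicate 1 could give such values but stayed untested, since Mir144 (-3.02) is itself part of the pattern. Mir486 (-0.15) did not follow it, and its value is uncertain because it shares bases with a copy. Shared transcription of Mir144 and Mir451a stays open too, and no biological explanation was tested with 1 group.

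The choroid plexus and ciliated cell list was higher in replicate 2 by its median, but 3 of 6 tested members passed (Mir204, Mir34b and Mir211, the last with 2 and 10 counts), Mir449a (0.80) and Mir34c (0.92) did not, and the median lay at the 97.1 percentile without Mir34b, Mir34c and the Mir449 genes. Counting error was excluded for Mir204, whose log2 ratio had a lower 95% bound of 1.71. Mir204 too had already passed the exact test on the same counts, so this bound is no second test. The 50 genes nearest to each member in hairpin GC content and length were pooled here too. Their median log2 ratio was 0.092 (95% bootstrap interval -0.02 to 0.23), against 1.44 for the list, so as a set they did not share the shift. This set is also too broad for its median to exclude GC content or length. The linear trend decided nothing here either, with a median of 1.40 once it was removed. More choroid plexus in the tissue of replicate 2 could give such values, and the 5 tested Htr2c intron microRNAs other than Mir1298 had a median log2 ratio of 1.02 with library totals, narrowly above the bound of 1 set in advance, with 5 above 0, 3 differing and the median at the 98.3 percentile of random lists matched on expression. The median lay below that bound with TMM sizes (0.95) and DESeq2 factors (0.84), where Mir448 no longer passed and 2 differed, so the margin is too small to carry weight. With Mir1912 (0 counts in replicate 1 and 25 in replicate 2) at its bound, the median was also 1.02 with library totals. That step could not move the median, since Mir1912 stays the highest of the 5. Mir1298 (3.27) had been seen before the Htr2c set was chosen, and the 5 genes lie in introns of the same host gene on the same strand. A high median could follow from that choice, so it is no independent support. Htr2c is active in neurons too, and Mir449a is also on the astrocyte list, so a difference in neurons or glia stays open. With 1 group no difference between groups was tested.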

How the results depend on the processing

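The alternatives that leave out genes with copies from the differing genes, members shared between lists from the astrocyte list, and Mir34b, Mir34c and the Mir449 genes from the choroid plexus list, and both rescalings of the Htr2c microRNAs, were chosen after seeing the data. No paired analysis was possible because there is 1 group.

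The let-7 share of 25.4% was 18.3% without the most abundant gene, which is Mirlet7b, a let-7 gene, and 27.6% without genes that have a near-identical copy. The number of differing genes was 101, against 59 with a filter of 100 counts in total and 301 with no minimum ratio, both by construction of the alternative. It was 96 with TMM sizes, of which 90 were shared with the 101, 99 with DESeq2 factors (83 shared), 111 with no filter, 96 with unstranded counts and 89 without genes with copies. Among named genes, Mir150, Mir29c and Mir3070a (the last pair with copies) no longer passed with TMM sizes or DESeq2 factors, nor Mir125a with DESeq2 factors, and Mir219a-1 passed with both. These ratios lie near 1 in absolute size, and each scaling shifts all of them by a constant.

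The astrocyte median was 0.95 at the 96.5 percentile without shared members, with 3 genes left, and the choroid plexus median was 2.16 at the 97.1 percentile without Mir34b, Mir34c and the Mir449 genes, with 2 left; fewer genes widen the range of random lists. The red blood cell, choroid plexus, miR-29 and astrocyte medians kept their direction and their place outside the 2.5 to 97.5 percentiles with TMM sizes, DESeq2 factors, 100 counts in total and unstranded counts. A rescaling moves every ratio by the same constant and can hardly move these percentiles. The filter left the members and medians of the red blood cell, miR-29 and astrocyte lists unchanged, so only their random lists could change. Unstranded counts kept all tested members of the choroid plexus, miR-29 and astrocyte lists and hardly moved their medians. The main test was thus of the choroid plexus list, which lost members to the filter and kept its place. For the red blood cell list, unstranded counts left Mir144 alone, since Mir451a and Mir486 then had 0 counts. No called result changed direction, and the rescalings could not have made one do so, since they moved ratios by far less than the minimum of 1.

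Leaving out each replicate gave 469 to 500 detected genes, a let-7 share of 23.96 to 26.84%, a Dlk1-Dio3 share of 21.1 to 24.1% and a neuronal share of 8.24 to 10.7%. Some smaller shares moved more in proportion, among them those of the miR-29 family (0.0729 to 0.182%) and of striated muscle (0.00483 to 0.0113%). Results that compare the libraries need both, so none was left out there. The coefficient of variation ranged from 36.6 to 42.8%, and detected genes from 312 at 10 CPM to 510 at 1 CPM. With unstranded counts 9 genes of at least 1000 CPM kept under 1% of their counts, among them Mirlet7e and Mir126a, because an opposite-strand gene makes their reads ambiguous.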

Other observations

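The test of spread within clusters was set out before its result was seen; the genes and families named in the next paragraphs were chosen after their values were seen.

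Htr2c, a serotonin receptor gene on the X chromosome, holds several microRNA genes in its introns. Mir448 had 209 counts in replicate 1 and 307 in replicate 2, Mir1264 had 135 and 152, and Mir764 had 59 and 108. Mir1912 had 0 and 25 counts. On chromosome 12, beyond the Dlk1-Dio3 clusters described, Mir1247 in an exon of Dio3os had 156 counts in replicate 1 and 1 in replicate 2.

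MicroRNA families with several genes differed in the counts assigned to them. The 2 Mir128 genes held 22089 and 27917 counts, the 3 Mir9 genes 510 and 336, the 2 Mir26a genes 85 and 1148, and the 3 Mir124a genes 17 and 17.

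A hypothesis was that the libraries differ at single microRNAs and not by whole genomic clusters. Over 12 clusters with 85 genes the mean within-cluster SD of the log2 ratio was 0.57, at the 5.2 percentile of 2000 random groupings matched on expression. The bound set in advance was the 5 percentile, so the value lies on the side of the hypothesis by a margin too small to carry weight, and a tendency of neighbours to differ together may be present.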
